A study of Caenorhabditis elegans with 30 samples.

How the data were processed

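Per the labels, total RNA was taken from Caenorhabditis elegans that were synchronised as L1 larvae and grown to young adults on bacteria carrying the empty RNAi vector L4440 or a vector against pmt-2, on plates with carbenicillin at 25 µg/mL and IPTG at 1 mM. The tunicamycin group was treated at 25 µg/mL for 4 h in M9 buffer. RNA was extracted with Trizol and an RNeasy column, and 300 ng per sample were amplified, labelled with biotin by the WT PLUS kit and hybridised to Affymetrix gene arrays, 1 array per sample. The 30 arrays form 10 groups of 3. The groups are wild type N2 on the empty vector, on pmt-2 RNAi and with tunicamycin, mutants of atf-6, ire-1 and pek-1 each on the empty vector and on pmt-2 RNAi, and a pmt-2 knockout whose sample title names the empty vector.

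The deposited value table holds log2 values per transcript cluster, which the authors made with RMA (background correction, quantile normalisation and summary of the probes). The labels give no version of RMA. The authors also deposited 12 tables that each compare a pair of groups. In these tables the deposited averages are biweight means of the log2 values, the deposited fold changes are a signed score (linear fold change with a minus sign for a decrease), and the authors' p-value comes from an ANOVA with an FDR-adjusted p-value beside it. In the deposited tunicamycin table the sign of the fold change was opposite to the difference of its averages in all 20753 clusters whose averages lay over 0.1 apart, and all 28387 unadjusted p-values carried a minus sign, so directions were taken from the averages. The source labels of the N2 pmt-2 RNAi and tunicamycin samples appear exchanged relative to their titles. The titles were used, and the level of pmt-2 followed them.

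The value table held 29317 clusters, of which 930 were absent from the comparison tables and were left out, so that 28387 clusters were tested. Of these, 25930 carried exactly 1 gene symbol, 651 several and 1806 none, and 6215 were described as noncoding RNA. In all arrays 538 clusters repeated the values of another cluster, and counts of clusters include them. Symbols were brought up to date with a RefSeq gene table, which was used for names only. A RefSeq accession named 22619 of the clusters with 1 symbol, a symbol or locus tag named 2958, and 353 kept the name of the file. Coordinates are those of the authors' files, which name no genome build. Array medians ran from 3.743 to 3.891, 25th percentiles from 2.352 to 2.593 and 75th percentiles from 6.251 to 6.435 on the log2 scale. Probe-level files and detection calls were not used here, and the number of arrays limits the precision.

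A linear model with a mean for each group was fitted to the log2 values of all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had 20 residual degrees of freedom, and the prior added 4.29. There were 14 comparisons. They were pmt-2 RNAi, tunicamycin and the pmt-2 knockout against N2 on the empty vector; each mutant against N2; pmt-2 RNAi within each mutant; the difference between that effect and the effect in N2 (the interaction); the knockout against pmt-2 RNAi in N2; and pmt-2 RNAi against tunicamycin in N2. A cluster was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples. Replicate numbers were not used as a block, since residuals of arrays with the same number were uncorrelated (mean r 0.006, -0.003 and 0.015 for the numbers, against -0.003 for different numbers). No pair of arrays was identical.

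Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists within each comparison. For genes with several clusters the cluster with the highest mean was used. The lists, with their measured genes, were ER chaperones and folding (24), ER-associated degradation (18), translocon and signal peptidase (14), N-glycosylation (22), COPI and COPII vesicle coats (17), the abu/pqn genes (28), phosphatidylcholine and one-carbon metabolism (30), fatty acid synthesis, desaturation and lipid storage (33), fatty acid beta-oxidation (31), fasting-induced metabolism (15), autophagy (33), lysosome (48), the cytosolic heat shock response (20), the mitochondrial stress response (21), oxidative stress and glutathione (38), cytochrome P450 and UDP-glucuronosyltransferase genes (47), innate immune effectors (56), vitellogenins (5), germline and oocyte (46), sperm (34), zygotic embryo (24), collagens and cuticle (70), molting (36), body wall and pharyngeal muscle (31), neurons (46), intestine (25), ribosomal proteins (79), proteasome (31) and tRNA synthetases (24). Camera was repeated with an inter-gene correlation estimated from the residuals. The lists, the tests, the named genes and all alternatives but 5 were fixed before the data were examined.

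Named genes were chosen by a rule. These were pmt-1, pmt-2, ire-1, xbp-1, pek-1, the atf-4 homologue atf-5, atf-6, hsp-3 and hsp-4 in every comparison, the 8 highest and 8 lowest called genes with a name of 3 or 4 letters, a hyphen and a number whose arrays all lay on the same side of the other group for the first 3 comparisons (4 and 4 for the rest), and the 3 members with the largest change in each list described. Other names are said to be chosen after their values were seen. Responses were compared by Pearson correlation and covariance across clusters, which are not independent replicates. The same quantities were computed on simulated arrays without any change, to show what shared control arrays give.

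The calls were tested on simulated data made with the spread of these arrays, with 200 of 28387 clusters changed. For pmt-2 RNAi in N2, 26.9% of 1.5-fold, 65.7% of 2-fold and 100% of 4-fold changes were recovered with 6 false calls. For the interaction with ire-1 the shares were 7.5%, 43.3% and 90.9% with 4 false calls. Over 25877 genes, camera called 0 of 100 random lists and 10 of 10 lists of 30 genes shifted by 0.5. The simulated genes were independent of each other, so this does not test calls for lists whose genes vary together.

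Alternatives were leaving out the lowest 25% of clusters by mean, cyclic loess between arrays, shifting arrays to a common median, eBayes with trend and robust settings, weights per array, a replicate block, a fold of at least 1.5 beside the adjusted p, 1 cluster per gene with 1 symbol, a fit to only the groups of a comparison, leaving out each array, and for the lists an estimated correlation, the fry test, a trend in the variance and the mean of a gene's clusters. Where leaving out an array left 2 in a group, the pooled spread was used. Array weights by gene, gene lists and overlaps without each array, tissue lists of the knockout after cyclic loess, and the molting list of the pek-1 interaction without each N2 RNAi array were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.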

Results

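Groups of Caenorhabditis elegans with RNAi against pmt-2 or its knockout differed from the N2 control in many transcript clusters, as did a group on tunicamycin, an inhibitor of N-glycosylation. The gene pmt-2 encodes a phosphoethanolamine methyltransferase of phosphatidylcholine synthesis. Of 28387 clusters, 4435 rose and 5032 fell with pmt-2 RNAi in wild type N2, 2340 rose and 2375 fell with tunicamycin, and 8074 rose and 8733 fell in the knockout, each against N2 on the empty vector. Fits to only the 2 groups called 5634, 2970 and 16448 clusters. Mutants of atf-6 and pek-1 on the empty vector differed from N2 in 55 and 32 clusters, and the ire-1 mutant in 1748. All values are log2 RMA intensities from 3 arrays per group; changes are log2 differences with the standard error (SE) of the fitted model, and group levels are means ± SD. The p-values measure the spread between these samples, because the labels do not say whether replicates were separate cultures.

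The first principal component held 56.9% of the variance and set the knockout arrays (178.1 to 179.3) apart from N2 on the empty vector (-55.2 to -47.7). The N2 pmt-2 RNAi arrays spread along it (-4.5, 38 and 8.4), and correlation between replicates was lowest in that group (0.98). The median change of all clusters lay at -0.133 in the knockout and -0.147 for pmt-2 RNAi in pek-1, so changes are relative to the deposited scaling of the arrays. Named genes followed rules set in advance. Rankings cover only clusters with a gene name of 3 or 4 letters, a hyphen and a number (ranked genes), so clusters with another name or none can have changed more. The size and rank of a change are rough where a group lies near the floor of the arrays, as for kreg-1 in the controls of its RNAi comparisons (2.42 in N2, 2.19 in atf-6 and 2.23 in pek-1). Of 100 named genes called for pmt-2 RNAi in N2, all but abu-14, abu-7 and med-2 had their 3 treated arrays beyond the 3 control arrays, which the rule itself required of the strongest ones. This held for all 88 named genes called with tunicamycin, all 63 in the ire-1 mutant and every named gene called in the knockout.

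**Figure D1:**
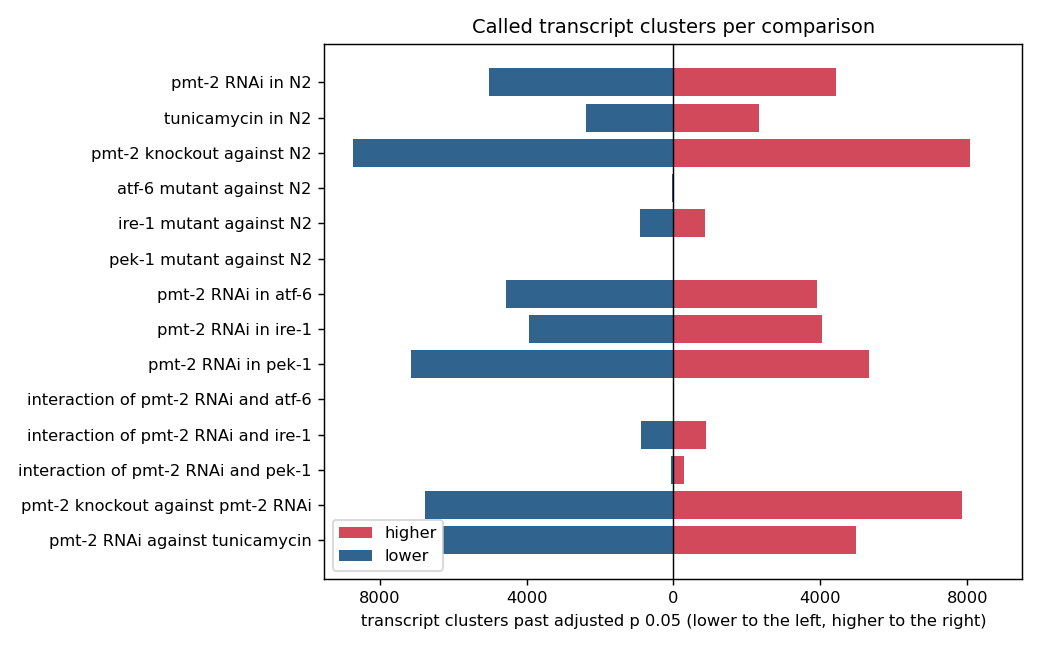
Number of clusters called higher or lower in each of the 14 comparisons at an adjusted p under 0.05. Each group holds 3 arrays.

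In N2, RNAi lowered its target pmt-2 (V: 4628566-4635252) from 10.14 ± 0.07 to 6.63 ± 0.17, a change of -3.51 (SE 0.11, adjusted p = 3e-17). The enzyme acting before it, pmt-1, rose from 9.97 ± 0.21 to 11.89 ± 0.11 (1.92, SE 0.1). Among the sensors and effectors of the unfolded protein response, pek-1, the PERK kinase, rose by 1.13 (SE 0.1), xbp-1, whose mRNA is spliced by IRE-1, by 0.80 (SE 0.09), and the transcription factor gene atf-6 by 0.69 (SE 0.1). The BiP homologues hsp-4 and hsp-3 rose by 0.58 (SE 0.14, adjusted p = 0.0015) and 0.53 (SE 0.11, adjusted p = 0.00046). For ire-1 (0.13, adjusted p = 0.357) and atf-5, the homologue of atf-4 (0.19, adjusted p = 0.243), the test was not passed.

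Among ranked genes the largest rise in N2 was that of warf-1 (IV: 7634821-7635696), an ARF-like GTPase gene, from 3.21 ± 0.34 to 10.09 ± 0.29 (6.88, SE 0.18, adjusted p = 1.8e-18). It was followed by the beta-tubulin gene tbb-6 (5.17, SE 0.16), kreg-1 (4.91, SE 0.29), the lysozyme gene lys-3 (4.79, SE 0.34), tsp-1 (4.12, SE 0.25), asp-17 (4.05, SE 0.19), cpr-3 (3.91, SE 0.16) and the desaturase gene fat-5 (3.83, SE 0.25). The strongest falls of ranked genes were those of pud-3 (V: 2324509-2326846; -4.99, SE 0.29), pud-4 (-4.80, SE 0.35), the yolk protein gene vit-1 (-4.66, SE 0.37), folt-2 (-4.59, SE 0.25), spp-4 (-4.30, SE 0.22), acdh-1 (-4.07, SE 0.3), asm-3 (-4.02, SE 0.22) and vit-4 (-3.98, SE 0.43).

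Genes of lipid synthesis and autophagy rose with pmt-2 RNAi in N2. In the list of fatty acid synthesis, desaturation and lipid storage, 21 of 33 genes rose and 5 fell over all genes, with the same counts adjusted over the list alone (median 0.64, adjusted p = 3.58e-08). The delta-9 desaturase genes fat-5, fat-7 and fat-6 rose by 3.83, 3.69 and 1.93. In the autophagy list 15 of 33 rose and none fell over all genes (17 and 1 adjusted over the list alone, median 0.32, adjusted p = 6.49e-07). Its largest rises were those of sqst-1, a p62-like receptor, at 3.31 (SE 0.1), atg-2 at 1.44 (SE 0.12) and hlh-30, the TFEB homologue, at 1.28 (SE 0.14). In the list of fasting-induced metabolism 10 of 15 rose and 1 fell, also when adjusted over the list alone (median 0.86, adjusted p = 7.84e-06). The gene acs-2, an acyl-CoA synthetase, rose by 3.36 (SE 0.24) and icl-1 of the glyoxylate cycle by 2.54 (SE 0.15). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.00543, 0.00543 and 0.0426). In the list of phosphatidylcholine and one-carbon metabolism 9 of 30 rose and 7 fell (10 and 7 adjusted over the list alone, median 0.08, adjusted p = 0.516), with the choline kinase gene ckb-2 at 1.80 (SE 0.23).

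In the ER chaperone and folding list 13 of 24 genes rose and 1 fell over all genes (13 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.000453, and adjusted p = 0.184 with an estimated correlation). Its largest changes were C14B9.2 at 1.36 (SE 0.1), the calreticulin gene crt-1 at 0.71 (SE 0.08) and enpl-1 at 0.66 (SE 0.08). In the list of COPI and COPII vesicle coats 9 of 17 rose and none fell (10 and 0 adjusted over the list alone, median 0.27, adjusted p = 0.000195, and adjusted p = 0.114 with an estimated correlation). In the translocon and signal peptidase list 7 of 14 fell and 1 rose, also adjusted over the list alone (median -0.25, adjusted p = 0.0276). That call was lost with cyclic loess (adjusted p = 0.121) and with an estimated correlation (adjusted p = 0.114). For ER-associated degradation, with 1 of 18 higher and 7 lower (3 and 7 adjusted over the list alone, median -0.07), the adjusted p was 0.181.

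Lists of molting genes, abu/pqn genes, neurons, germline and sperm moved beside these groups in N2. The labels give the stage only as young adult. A difference in stage between RNAi and control animals was therefore not separated from the other changes with pmt-2 RNAi. In the molting list 24 of 36 rose and 1 fell (27 and 1 adjusted over the list alone, median 1.1, adjusted p = 3.58e-08, and adjusted p = 0.245 with an estimated correlation), with peb-1 at 3.05 (SE 0.25). In the abu/pqn list 17 of 28 rose (18 adjusted over the list alone, median 0.98, adjusted p = 7.84e-06, and adjusted p = 0.239 with an estimated correlation), including abu-14 at 2.05 (SE 0.38). Its median relative to N2 on the empty vector was 0.13, 1.77 and 0.87 in the 3 RNAi arrays. Without N2 pmt-2 RNAi array 2 or N2 empty-vector array 3 abu-7 (1.58, SE 0.46) was no longer called (0.85 and 1.28). In the neuron list 35 of 46 rose and 1 fell (36 and 1 adjusted over the list alone, median 0.82, adjusted p = 1.34e-18, and adjusted p = 0.0516 with an estimated correlation), with nlp-9 at 2.37 (SE 0.13). In the germline and oocyte list 29 of 46 fell and 1 rose (34 and 1 adjusted over the list alone, median -0.44, adjusted p = 5.82e-06, and adjusted p = 0.325 with an estimated correlation). In the sperm list 15 of 34 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.54, adjusted p = 0.000297, and adjusted p = 0.201 with an estimated correlation). The 3 RNAi arrays had sperm list medians of 0.14, 0.77 and 0.52 relative to N2 on the empty vector. The lists of collagens and cuticle (median 0.28, at -0.37, 0.94 and 0.26 in the 3 RNAi arrays, adjusted p = 0.683), body wall and pharyngeal muscle (0.17, adjusted p = 0.222), intestine (-0.13, adjusted p = 0.611) and zygotic embryo (-0.15, adjusted p = 0.567) were not called.

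Tunicamycin raised hsp-4 from 9.76 ± 0.16 to 10.65 ± 0.07 (0.89, SE 0.14, adjusted p = 2.1e-05), xbp-1 by 0.52 (SE 0.09), atf-6 by 0.52 and pmt-1 by 0.50. In the same arrays pmt-2 fell by 1.44 (SE 0.11) and atf-5 by 1.14 (SE 0.12). A rise of pek-1 (0.33, SE 0.1, adjusted p = 0.0303) was lost without N2 empty-vector array 1 or 2 (0.26 and 0.31), without tunicamycin array 1 or 3 (0.26 and 0.35) and after a shift to a common median (0.30). For ire-1 (0.14, adjusted p = 0.405) and hsp-3 (0.25, adjusted p = 0.131) the test was not passed. The treated animals were held in buffer for 4 h, which the labels do not state for the controls, so the comparison also holds that difference.

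The largest rise of a ranked gene with tunicamycin was that of the metallothionein gene mtl-1 (V: 6691352-6691846) from 4.59 ± 0.19 to 9.82 ± 0.21 (5.23, SE 0.17, adjusted p = 1.3e-16). Others were ckb-2 (3.61, SE 0.23), scl-2 (3.60, SE 0.17), dpy-14 (3.53, SE 0.54), ugt-18 (3.52, SE 0.27), egl-46 (3.37, SE 0.34), nlp-28 (3.30, SE 0.19) and hch-1 (3.27, SE 0.53). Falls of ranked genes were led by folt-2 (V: 2872463-2875598; -4.51, SE 0.25), the collagen genes col-103 (-4.14, SE 0.19), col-98 (-4.04, SE 0.18) and col-93 (-3.90, SE 0.38), abhd-3.2 (-4.08, SE 0.16), ugt-63 (-4.03, SE 0.18), spp-23 (-3.98, SE 0.24) and dod-19 (-3.53, SE 0.18).

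With tunicamycin 12 of 24 ER chaperone genes rose and 1 fell over all genes (17 and 1 adjusted over the list alone, median 0.34, adjusted p = 3.73e-11), led by C14B9.2 at 1.81 (SE 0.1) and dnj-27 at 1.75 (SE 0.12). In the autophagy list 21 of 33 rose and 1 fell (22 and 1 adjusted over the list alone, median 0.32, adjusted p = 2.54e-09). Among them were epg-2 at 2.49 (SE 0.3), sqst-1 at 1.68 and the ATG8 homologue lgg-1 at 1.18 (SE 0.1). The fatty acid list moved opposite to its direction under pmt-2 RNAi. In it 16 of 33 fell and 5 rose (18 and 5 adjusted over the list alone, median -0.32, adjusted p = 1.62e-08), with the elongase genes elo-5 at -2.61 (SE 0.1) and elo-6 at -2.49 (SE 0.09). In the phosphatidylcholine and one-carbon list 12 of 30 fell and 4 rose, also adjusted over the list alone (median -0.11, adjusted p = 0.00243); sams-1, which encodes an S-adenosylmethionine synthetase, fell by 3.20 (SE 0.12). The translocon list fell (8 of 14 lower, 1 higher; 8 and 2 adjusted over the list alone, median -0.38, adjusted p = 0.000666), with trap-1 at -0.92 (SE 0.09). Of the cytosolic heat shock genes 11 of 20 fell and 3 rose (13 and 3 adjusted over the list alone, median -0.35, adjusted p = 4.28e-05), with hsp-70 at -3.09. Lysosome genes fell in 25 of 48 cases and rose in 8 (27 and 10 adjusted over the list alone, median -0.36, adjusted p = 1.36e-07). Of the cytochrome P450 and UDP-glucuronosyltransferase genes 18 of 47 fell and 5 rose (21 and 6 adjusted over the list alone, median -0.34, adjusted p = 2.16e-05). These 8 lists kept their calls with an estimated correlation, at adjusted p from 0.00194 to 0.0368.

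Among tissue markers, 41 of 70 collagen and cuticle genes fell with tunicamycin and 6 rose (48 and 8 adjusted over the list alone, median -0.95, adjusted p = 5.47e-15, and adjusted p = 0.146 with an estimated correlation). In the muscle list 19 of 31 fell and 1 rose (22 and 1 adjusted over the list alone, median -0.46, adjusted p = 5.75e-10, and adjusted p = 0.135 with an estimated correlation). In the intestine list 12 of 25 fell and 4 rose (14 and 5 adjusted over the list alone, median -0.34, adjusted p = 0.000756, and adjusted p = 0.127 with an estimated correlation), with act-5 at -3.26 (SE 0.18). In the zygotic embryo list 14 of 24 rose and none fell (15 and 2 adjusted over the list alone, median 0.59, adjusted p = 1.11e-07, and adjusted p = 0.0534 with an estimated correlation), with sdz-28 at 2.36 (SE 0.3). The N-glycosylation list had 1 of 22 genes lower and none higher, with the same counts adjusted over the list alone (median 0.02, adjusted p = 0.972). The list of ER-associated degradation had 2 of 18 higher (median 0.04, adjusted p = 0.282).

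**Figure D2:**
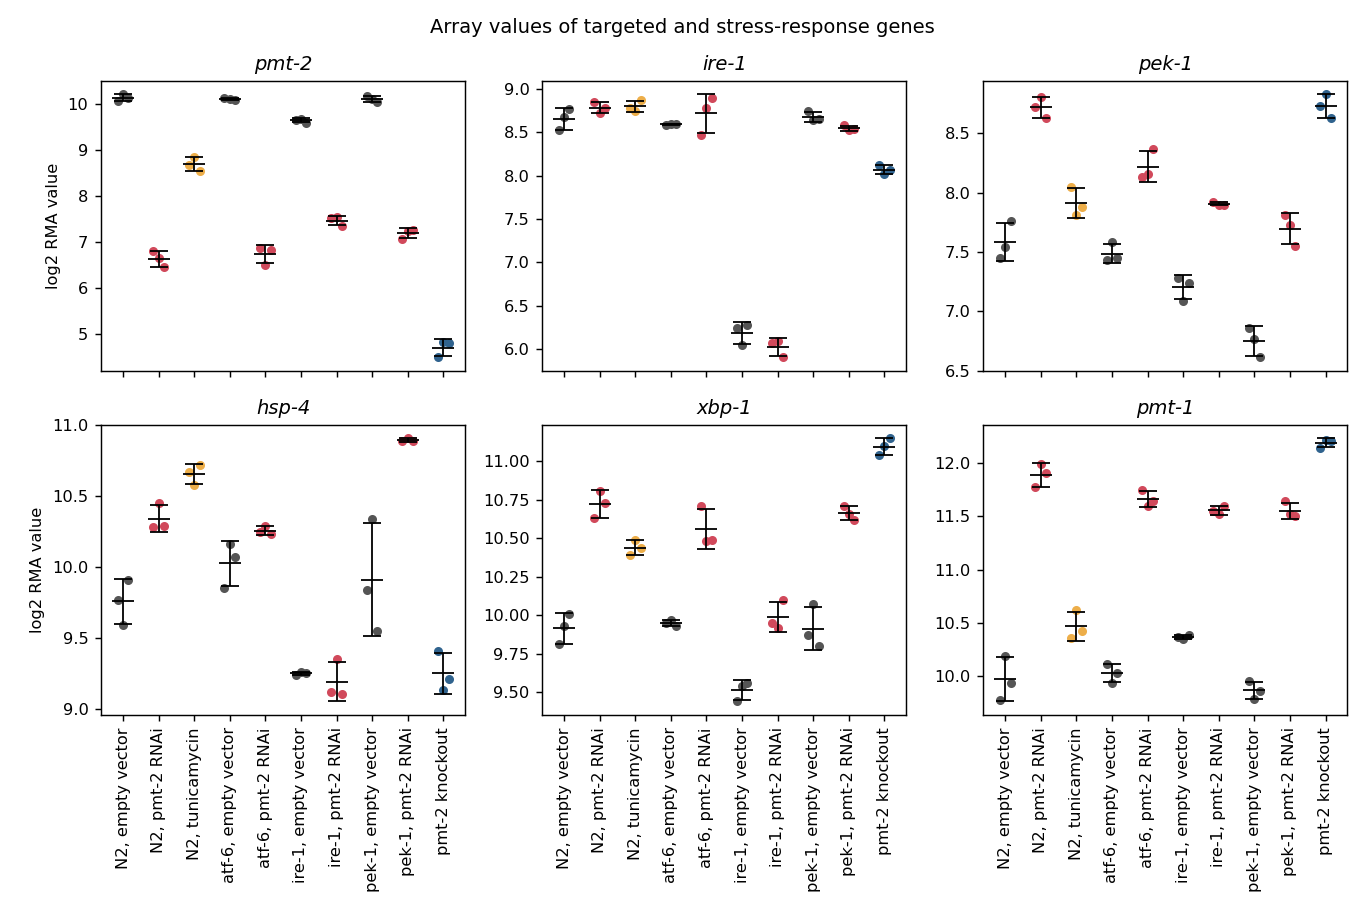
Array values (points), mean and SD (bars) of pmt-2, ire-1, pek-1, hsp-4, xbp-1 and pmt-1 in the 10 groups on the log2 RMA scale. Each group holds 3 arrays.

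In the pmt-2 knockout pmt-2 stood at 4.70 ± 0.18 against 10.14 ± 0.07 in N2 (-5.44, SE 0.11, adjusted p = 1.1e-22). Its paralogue pmt-1 rose by 2.22, atf-6 by 1.83, xbp-1 by 1.18, pek-1 by 1.14 and atf-5 by 0.70. The BiP homologues parted: hsp-3 rose by 0.34 (adjusted p = 0.0103) and hsp-4 fell by 0.51, to 9.25 ± 0.14 (adjusted p = 0.0022), and ire-1 fell by 0.59 (adjusted p = 1e-05). The falls of hsp-4 and ire-1 were lost with cyclic loess (-0.04 and -0.16), and the rise of hsp-3 after a shift to a common median (0.21) or without N2 empty-vector array 1 (0.28).

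The knockout animals lost most signal from yolk protein genes. In N2 vit-5 (X: 3403457-3408591) stood at 12.82 ± 0.03 and in the knockout at 2.92 ± 0.38 (-9.89, SE 0.18, adjusted p = 1e-23). The other strongest falls of ranked genes were vit-6 (-9.35, SE 0.18), vit-2 (-8.28, SE 0.12), col-81 (-8.14, SE 0.35), ule-3 (-8.12, SE 0.09), col-124 (-7.80, SE 0.11), the oocyte RNA-binding protein gene puf-5 (-7.75, SE 0.18) and vit-1 (-7.66, SE 0.37). Their largest rises were in clec-17 (I: 12430019-12431464; 7.11, SE 0.25), clec-174 (6.26, SE 0.34), lys-3 (6.16, SE 0.34), tsp-1 (6.12, SE 0.25), lpr-3 (5.73, SE 0.5), col-41 (5.70, SE 0.21), meic-1 (5.69, SE 0.36) and ugt-18 (5.54, SE 0.27). All 46 germline and oocyte genes fell over all genes and adjusted over the list alone (median -5.42, adjusted p = 3.05e-30). All 5 vitellogenins fell as well (median -8.28, adjusted p = 1.81e-05, and adjusted p = 0.0554 with an estimated correlation). In the neuron list 45 of 46 rose, also adjusted over the list alone (median 2.85, adjusted p = 2.49e-22), with flp-2 at 4.09 (SE 0.21). In the molting list 33 of 36 rose and 2 fell, also adjusted over the list alone (median 3.05, adjusted p = 1.93e-09, and adjusted p = 0.2 with an estimated correlation). In the sperm list 27 of 34 fell (29 adjusted over the list alone, median -0.85, adjusted p = 0.000223, and adjusted p = 0.173 with an estimated correlation). In the collagen list 32 of 70 rose and 34 fell, also adjusted over the list alone (median -0.44, adjusted p = 0.229).

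In the autophagy list 19 of 33 genes rose in the knockout and 5 fell (19 and 6 adjusted over the list alone, median 0.51, adjusted p = 0.00101, and adjusted p = 0.0554 with an estimated correlation). The largest rises were sqst-1 at 3.62, hlh-30 at 2.53 and atg-2 at 2.30. In the fatty acid list 17 of 33 rose and 7 fell (17 and 8 adjusted over the list alone, median 0.68, adjusted p = 0.0143, and adjusted p = 0.151 with an estimated correlation). Here fat-5 stood at 3.21, fat-3 at 2.35 and fat-7 at 2.29. In the ER chaperone list 13 of 24 rose and 6 fell, also adjusted over the list alone (median 0.29, adjusted p = 0.238); with cyclic loess it was called (adjusted p = 0.00398). Other lists of the secretory pathway fell, each with the same counts adjusted over the list alone. Such falls were not particular to this pathway, since the proteasome and tRNA synthetase lists, given further below, fell by similar medians. Of the translocon genes 12 of 14 fell and 1 rose (median -0.89, adjusted p = 0.000513). Of the N-glycosylation genes 19 of 22 fell and 1 rose (median -0.84, adjusted p = 0.000146, and adjusted p = 0.13 with an estimated correlation). Of the genes of ER-associated degradation 16 of 18 fell (median -0.81, adjusted p = 0.000257, and adjusted p = 0.13 with an estimated correlation). The translocon, germline and neuron lists kept their calls with an estimated correlation (adjusted p = 0.0256, 0.0375 and 0.0375).

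**Figure D3:**
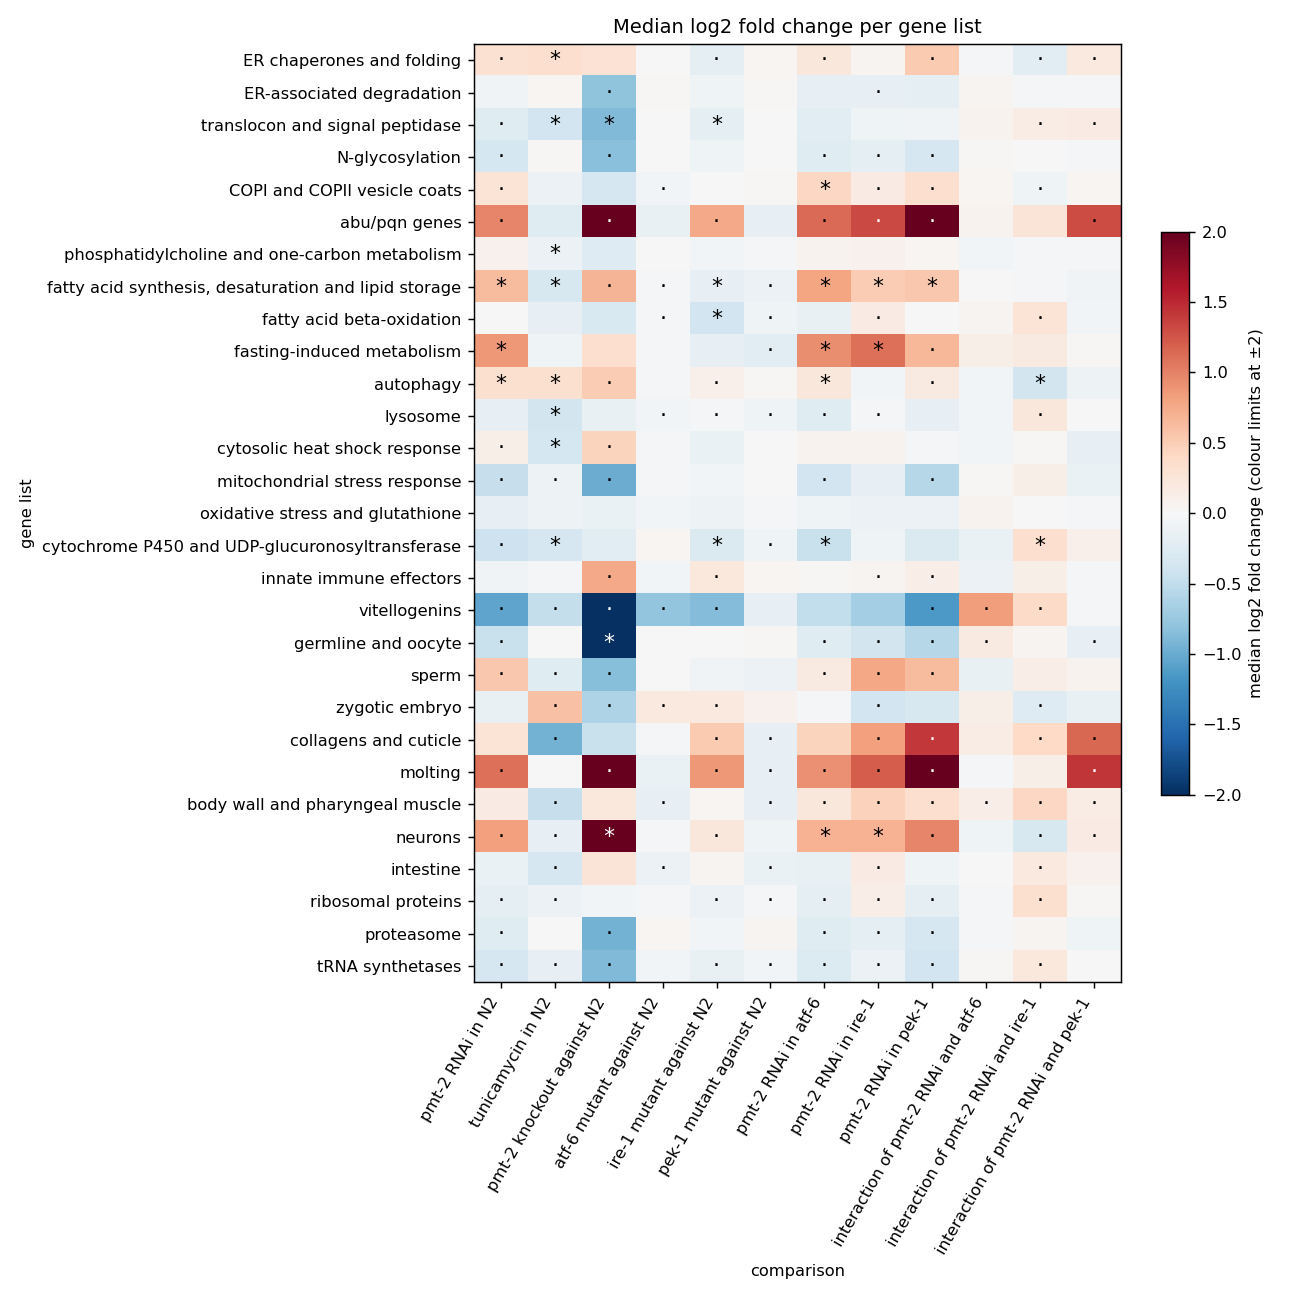
Median log2 change of the 29 gene lists in the first 12 comparisons, with colour limits at -2 and 2. A dot marks a call at the preset correlation and an asterisk a call also with an estimated correlation.

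The knockout was compared with pmt-2 RNAi directly, and 7856 clusters were higher and 6760 lower in the knockout. Residual pmt-2 was lower by 1.93, hsp-4 was lower by 1.09 (SE 0.14, adjusted p = 1.5e-07) and ire-1 by 0.72. In contrast atf-6 was higher by 1.14, atf-5 by 0.51 and xbp-1 by 0.37, and pek-1 (0.01, adjusted p = 0.947) and hsp-3 (-0.19, adjusted p = 0.153) did not pass. A higher level of pmt-1 (0.30, adjusted p = 0.0123) was lost without N2 pmt-2 RNAi array 1 (0.24). The largest differences of ranked genes were in clec-174 (6.52), clec-17 (5.97), col-41 (5.32) and clec-72 (4.74), and in vit-6 (-8.98), vit-5 (-8.83), vit-2 (-8.26) and ule-3 (-8.06). All 46 germline genes were lower (median -4.91, adjusted p = 6.19e-39), as were 29 of 34 sperm genes (median -1.58, adjusted p = 2.43e-09), and 44 of 46 neuron genes were higher (median 1.87, adjusted p = 1.38e-19). Each list had the same counts adjusted over the list alone and a call with an estimated correlation (adjusted p = 0.0166, 0.0455 and 0.0455). In the collagen list 29 of 70 were higher and 34 lower (31 and 34 adjusted over the list alone), with a median of -0.07, a mean of -1.13 and adjusted p = 0.0132 (adjusted p = 0.635 with an estimated correlation).

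Between pmt-2 RNAi and tunicamycin in N2, 4969 clusters were higher with RNAi and 6310 lower, and a fit to only these 2 groups called 7488. With RNAi pmt-1 was higher by 1.42, atf-5 by 1.33 and pek-1 by 0.80, and pmt-2 was lower by 2.07; hsp-4 (-0.31, adjusted p = 0.0702) and atf-6 (0.17, adjusted p = 0.198) did not pass. The differences of xbp-1 (0.28, adjusted p = 0.014) and hsp-3 (0.28, adjusted p = 0.0464) were lost after a shift to a common median (0.24 and 0.23) and without N2 pmt-2 RNAi array 2 (0.24 and 0.22). That of hsp-3 was lost also without N2 pmt-2 RNAi array 1 (0.24), tunicamycin array 2 (0.21) or 3 (0.28). The desaturase gene fat-7 (V: 7151337-7153127) was higher by 5.70 (SE 0.18), at 12.25 ± 0.2 with RNAi and 6.55 ± 0.54 with tunicamycin, followed among ranked genes by warf-1 (5.65), tbb-6 (5.03) and dod-19 (4.85). Genes lower with RNAi were pud-4 (-4.85), mtl-1 (-4.71), pud-3 (-3.82) and asm-3 (-3.35). In the fatty acid list 27 of 33 genes were higher and 3 lower (median 0.99, adjusted p = 2.37e-19). In the heat shock list 12 of 20 were higher and 1 lower (median 0.30, adjusted p = 1.88e-05), both with the same counts adjusted over the list alone. In the neuron list 39 of 46 were higher and 1 lower (41 and 1 adjusted over the list alone, median 0.94, adjusted p = 2.3e-22). These calls held with an estimated correlation (adjusted p = 4.63e-05, 0.025 and 0.0355). The autophagy list was not called (11 of 33 higher, 8 lower, median -0.15 with a test towards higher values, adjusted p = 0.337), nor was the ER chaperone list (2 of 24 higher, 11 lower, median -0.28, adjusted p = 0.0553).

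The responses to pmt-2 RNAi and tunicamycin in N2 shared 1030 clusters that rose in both and 887 that fell in both, against 366 and 421 if the calls were independent, while 630 rose with RNAi but fell with tunicamycin (371 if independent) and 79 fell with RNAi but rose with tunicamycin (415 if independent). Across all clusters the correlation was 0.242 and the covariance 0.071. Both responses use the same 3 control arrays, and arrays simulated without any change gave a correlation of 0.507 and a covariance of 0.02, so a part of the overlap comes from the controls. For pmt-2 RNAi and the knockout 3315 clusters rose in both and 4110 fell in both (1261 and 1548 if independent), with a correlation of 0.6 and a covariance of 0.502 (0.505 and 0.019 in simulated arrays).

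Loss of the sensor genes on the empty vector was examined next. In the ire-1 mutant ire-1 (II: 8112214-8124788) fell by 2.47, from 8.66 ± 0.12 to 6.19 ± 0.13 (SE 0.1, adjusted p = 7.5e-15). In the pek-1 mutant pek-1 (X: 11410117-11414747) fell by 0.84, from 7.59 ± 0.16 to 6.74 ± 0.13 (SE 0.1, adjusted p = 0.00011). In the atf-6 mutant atf-6 (X: 12480880-12484811) stood at 7.28 ± 0.24 against 7.51 ± 0.12 (-0.23, adjusted p = 0.467); whether its probes lie in the deleted part is not known. In all 3 mutants bcf-1 (V: 6401352-6408767) fell, by 6.63, 6.40 and 6.36 in atf-6, ire-1 and pek-1, and gfi-1 (V: 6392519-6399904) rose by 3.34, 3.60 and 3.86.

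In the ire-1 mutant 845 clusters rose and 903 fell (638 and 1390 after a shift to a common median), and a fit to only these 2 groups called 834. Small falls of xbp-1 (-0.40, adjusted p = 0.0059), pmt-2 (-0.50, adjusted p = 0.0077), hsp-3 (-0.43, adjusted p = 0.0153), hsp-4 (-0.51, adjusted p = 0.0228) and pek-1 (-0.38, adjusted p = 0.0274) and a rise of pmt-1 (0.40, adjusted p = 0.0126) were called. The call of hsp-4 was lost without N2 empty-vector array 1 or 3 or any ire-1 empty-vector array (-0.44 to -0.52), and that of hsp-3 without N2 array 2 or 3 or ire-1 array 2 or 3 (-0.39 to -0.42). Leaving out the arrays that ended the call of hsp-3 also ended that of pek-1 (-0.29 to -0.40), as did cyclic loess (-0.32). The call of pmt-1 was lost without N2 array 1 or 3 (0.30 and 0.39). Beyond gfi-1 and bcf-1 the largest changes of ranked genes were in wrt-10 (2.77, SE 0.33), tbb-6 (2.69, SE 0.16), lpr-3 (2.50, SE 0.5), col-98 (-5.33, SE 0.18), aman-1 (-3.35, SE 0.14) and fat-7 (-3.17, SE 0.18). The receptor gene sqst-1 rose from 6.91 ± 0.2 to 8.28 (1.37, SE 0.1, adjusted p = 2.2e-09).

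Lipid and detoxification lists fell in the ire-1 mutant. For beta-oxidation 13 of 31 genes fell and 2 rose over all genes (19 and 3 adjusted over the list alone, median -0.38, adjusted p = 2.52e-11), with acdh-1 at -1.74 (SE 0.3). For fatty acid synthesis 9 of 33 fell and none rose (10 and 0 adjusted over the list alone, median -0.16, adjusted p = 3.11e-07). Of the cytochrome P450 and UDP-glucuronosyltransferase genes 16 of 47 fell (21 and 3 rose adjusted over the list alone, median -0.29, adjusted p = 2.35e-09). The translocon list had no gene called over all genes and 6 of 14 lower adjusted over the list alone (median -0.20, adjusted p = 0.00536). These 4 kept their calls with an estimated correlation (adjusted p from 0.00229 to 0.0363). In the ER chaperone list 7 of 24 fell (9 lower and 1 higher adjusted over the list alone, median -0.18, adjusted p = 0.000191, and adjusted p = 0.141 with an estimated correlation), with dnj-7 at -0.82 (SE 0.1). In the autophagy list 3 of 33 rose (5 adjusted over the list alone, median 0.10, adjusted p = 0.0121, and adjusted p = 0.141 with an estimated correlation). In the molting list 19 of 36 rose (24 adjusted over the list alone, median 0.86, adjusted p = 5.06e-14, and adjusted p = 0.141 with an estimated correlation). In the abu/pqn list 9 of 28 rose (14 adjusted over the list alone, median 0.76, adjusted p = 9.59e-12, and adjusted p = 0.093 with an estimated correlation).

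In the atf-6 mutant 23 clusters rose and 32 fell (16 and 54 after a shift to a common median), and 2866 had an unadjusted p under 0.05. A fit to only these 2 groups called 5. Beside bcf-1 and gfi-1, the ABC transporter gene haf-6 fell by 1.76 (SE 0.14), acdh-2 by 1.66 (SE 0.22), the filamin gene fln-2 by 1.34 (SE 0.14) and vit-2 (X: 5101001-5106142) by 0.82 (SE 0.12). Rises of ckb-2 (1.35, SE 0.23), srlf-30 (0.92, SE 0.17) and fbxa-154 (0.81, SE 0.16) were each lost without N2 empty-vector array 2 (1.2, 0.83 and 0.85). Those of srlf-30 and fbxa-154 were lost also without N2 array 1 (0.83 and 0.80) and atf-6 array 1 (0.87 and 0.84) or 2 (0.90 and 0.61), and that of fbxa-154 without N2 array 3 (0.77). The count fell to 26 and 25 without N2 array 2 and 3 and to 30 without atf-6 array 1. The vitellogenin list fell, with 1 of 5 lower over all genes and 3 adjusted over the list alone (median -0.79, adjusted p = 6.24e-07, and adjusted p = 0.1 with an estimated correlation). The muscle list had no gene called over all genes and 5 of 31 lower adjusted over the list alone (median -0.17, adjusted p = 1.41e-07, and adjusted p = 0.614 with an estimated correlation).

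In the pek-1 mutant 20 clusters rose and 12 fell, with 2404 at an unadjusted p under 0.05. A fit to only these 2 groups called 5. The calls of the full fit included haf-6 (-1.68), pdpr-1 (-1.55, SE 0.08), fln-2 (-1.1), srlf-30 (1.27), dnbp-1 (0.76) and asns-2 (0.69, SE 0.13). The call of asns-2 was lost without any N2 empty-vector array (0.65, 0.74 and 0.69) or pek-1 array 2 (0.55) and after a shift to a common median (0.66). Apart from pek-1 itself, none of pmt-1, pmt-2, ire-1, xbp-1, atf-5, atf-6, hsp-3 and hsp-4 was called in the pek-1 mutant, and none of these or pek-1 in the atf-6 mutant. In the pek-1 mutant 11 lists were called and none with an estimated correlation. The lowest adjusted p was that of muscle, with 0 of 31 genes called over all genes or adjusted over the list alone (median -0.16, adjusted p = 2.22e-06, and adjusted p = 0.461 with an estimated correlation).

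In the atf-6 mutant RNAi lowered pmt-2 by 3.37 (SE 0.11, adjusted p = 1e-16), from 10.11 to 6.74, and 3912 clusters rose and 4566 fell. In this mutant pmt-1 rose by 1.63, atf-6 by 1.26 (SE 0.1), hsp-3 by 0.74, pek-1 by 0.73 and xbp-1 by 0.61, while hsp-4 (0.23, adjusted p = 0.225) and ire-1 (0.13, adjusted p = 0.361) did not pass. Large changes were warf-1 (6.07, SE 0.18), kreg-1 (4.71), dbd-13 (4.16), fat-7 (4.11, SE 0.18), acdh-1 (-4.83), folt-2 (-4.73), spp-4 (-3.92) and pud-4 (-3.89). The autophagy list rose with 14 of 33 higher and 1 lower (16 and 1 adjusted over the list alone, median 0.23, adjusted p = 6.08e-07). The fatty acid list rose with 20 of 33 higher and 4 lower (21 and 6 adjusted over the list alone, median 0.79, adjusted p = 2.39e-10). Both held with an estimated correlation (adjusted p = 0.00573 and 0.00275).

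The RNAi effects in atf-6 and N2 correlated at 0.874 with a slope of 0.819, and they share no arrays (-0.003 in simulated arrays; covariance 0.295). The interaction was called for 8 clusters, all of which fell in N2 and fell less or not at all in atf-6, and 1950 had an unadjusted p under 0.05. The 8 are 6 distinct measurements, since 3 have the same values in all arrays, and a fit to only the 4 groups called none. They included bcf-1 (1.82, SE 0.32, adjusted p = 0.0325), which fell in N2 but lay near the floor of the array in both mutant groups (2.93 and 2.65), swt-3 (1.25, SE 0.19), acdh-2 (1.65, SE 0.31) and nhr-43 (0.97, SE 0.18). With cyclic loess acdh-2 (1.68) and nhr-43 (0.95) were not called. Without N2 empty-vector array 2, N2 pmt-2 RNAi array 3 or atf-6 empty-vector array 2 no cluster was called (bcf-1 at 1.76, 1.80 and 1.90). Without N2 empty-vector array 3 there were 3, without atf-6 empty-vector array 1 or 3 there were 4 and 2, and without atf-6 RNAi array 2 or 3 there was 1. No vitellogenin was called over all genes and all 5 were higher adjusted over the list alone (median 0.83, adjusted p = 6.95e-07, and adjusted p = 0.0871 with an estimated correlation). The autophagy list (median -0.05, adjusted p = 0.343) and ER chaperone list (median -0.02, adjusted p = 0.802) were not called.

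In the ire-1 mutant RNAi lowered pmt-2 by 2.18 (SE 0.11, adjusted p = 5.2e-12), from 9.65 ± 0.05 to 7.47 ± 0.11, against 6.63 ± 0.17 in N2 on RNAi. Here 4052 clusters rose and 3923 fell. Rises were seen in pmt-1 (1.18), pek-1 (0.70), xbp-1 (0.47) and atf-6 (0.38), and in atf-5 (0.42, adjusted p = 0.011), whose call was lost without ire-1 empty-vector array 3 (0.36). The values of hsp-4 (-0.06, adjusted p = 0.8), hsp-3 (0.16, adjusted p = 0.314) and ire-1 (-0.17, adjusted p = 0.214) did not pass. The desaturase gene fat-7 rose from 5.39 to 10.46 (5.07, SE 0.18, adjusted p = 1.1e-15), fat-5 by 3.26 (SE 0.25), warf-1 by 2.93 (SE 0.18) and cdh-7 by 2.48 (SE 0.34). Called falls included sdz-25, which fell by 1.94 (SE 0.45), and ces-2, which fell by 1.88 (SE 0.29). A fall of dpy-14 (-1.96, SE 0.54) was lost without ire-1 empty-vector array 3 (-1.59).

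In the ire-1 mutant 22 of 33 fatty acid genes rose with RNAi and 1 fell (23 and 1 adjusted over the list alone, median 0.50, adjusted p = 2.2e-15). Of the fasting genes 11 of 15 rose and 1 fell, also adjusted over the list alone (median 1.1, adjusted p = 5.53e-11). In the neuron list 32 of 46 rose and 1 fell (38 and 2 adjusted over the list alone, median 0.69, adjusted p = 1.18e-20). These 3 held with an estimated correlation (adjusted p = 0.00023, 0.00245 and 0.0476). The autophagy list was not called: 8 of 33 were higher and 4 lower (9 and 4 adjusted over the list alone), with a median of -0.05 and a test towards higher values (adjusted p = 0.331). In the ER chaperone list 5 of 24 were higher (4 adjusted over the list alone, median 0.05, adjusted p = 0.069), and with cyclic loess the list was called (adjusted p = 0.0285). The lysosome list was called higher (15 of 48 higher, 8 lower; 17 and 8 adjusted over the list alone; adjusted p = 0.0319, and adjusted p = 0.404 with an estimated correlation), with a median of -0.03 and a mean of 0.16.

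The interaction with ire-1 was called for 1775 clusters, 885 with a positive and 890 with a negative difference (RNAi effect in ire-1 less that in N2), and a fit to only the 4 groups called 1096. The effect on pmt-2 itself differed by 1.33 (SE 0.16, adjusted p = 3.5e-06) and that on pmt-1 by -0.74 (SE 0.14, adjusted p = 0.0012). A difference for hsp-4 (-0.64, SE 0.19, adjusted p = 0.0466) was lost after a shift to a common median (-0.57) and without any array of the 4 groups (-0.56 to -0.67) except N2 empty-vector array 3 and ire-1 RNAi array 2. For xbp-1 (-0.33, adjusted p = 0.148), pek-1 (-0.43, adjusted p = 0.0906) and hsp-3 (-0.37, adjusted p = 0.194) the test was not passed. Negative differences of ranked genes were led by warf-1 (-3.95, SE 0.26), tbb-6 (-3.78, SE 0.23), asp-17 (-3.75, SE 0.26) and kreg-1 (-3.57, SE 0.42), and positive ones by pud-3 (3.96, SE 0.41), pud-4 (3.53, SE 0.49), vit-1 (3.27, SE 0.53) and dhs-26 (3.03, SE 0.34). The 4 named genes with negative differences had risen in N2, and pud-3, pud-4 and vit-1 had fallen there. Of clusters called in N2, 761 that rose and 724 that fell had a smaller effect in ire-1, and 6 and 0 a larger effect. Choosing clusters by their N2 calls favours smaller effects elsewhere. In atf-6 the counts were 0 and 8 smaller and none larger, and in pek-1 26 and 45 smaller and 1.2e+02 (rounded) and 7 larger.

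**Figure D4:**
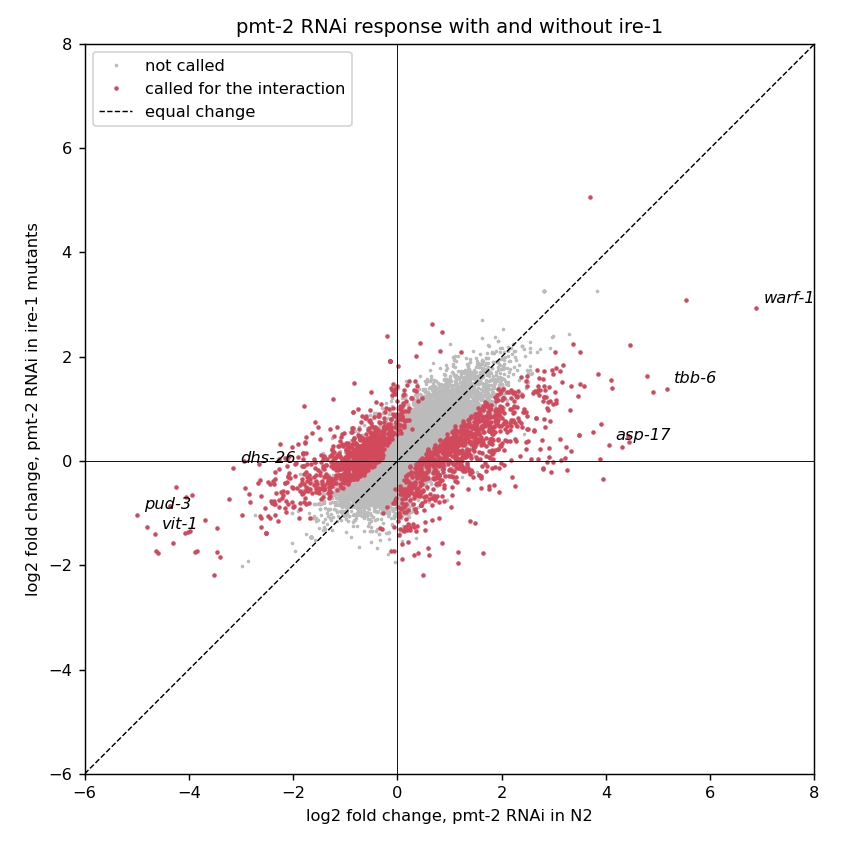
Change with pmt-2 RNAi in N2 (horizontal) and in the ire-1 mutant (vertical) for each cluster, with called interactions in red. The diagonal marks an equal change.

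The autophagy list had a lower RNAi effect in ire-1, with 10 of 33 genes lower and none higher over all genes (13 and 0 adjusted over the list alone, median -0.37, adjusted p = 9.91e-12). It held with an estimated correlation (adjusted p = 0.000376). On RNAi pmt-2 stood at 7.47 in ire-1 and 6.63 in N2, so a weaker knockdown and loss of ire-1 are not separated here. A difference in stage is not separated from them either. The difference for sqst-1 (IV: 12034230-12037029) was -2.35 (SE 0.15, adjusted p = 2.6e-10): it went from 8.28 to 9.25 in ire-1 and from 6.91 to 10.22 in N2. For the ATG8 homologue lgg-2 it was -0.77 (SE 0.11), and for epg-2 -1.49 (SE 0.42, adjusted p = 0.032). The call of epg-2 was lost after a shift to a common median (-1.42) and without N2 empty-vector array 2, N2 RNAi array 1 or 3, ire-1 empty-vector array 1 or 3 or ire-1 RNAi array 1 or 3 (-1.15 to -1.47). The cytochrome P450 and UDP-glucuronosyltransferase list had 14 of 47 higher and 3 lower (19 and 4 adjusted over the list alone, median 0.33, adjusted p = 3.47e-06, and adjusted p = 0.0461 with an estimated correlation), with cyp-25A1 at 2.33. The ribosomal protein list had 26 of 79 higher (38 adjusted over the list alone, median 0.32, adjusted p = 8.93e-19, and adjusted p = 0.186 with an estimated correlation). The beta-oxidation list had 9 of 31 higher and 4 lower (12 and 6 adjusted over the list alone, median 0.27, adjusted p = 8.17e-05, and adjusted p = 0.0665 with an estimated correlation). The ER chaperone list had 6 of 24 lower (11 lower and 3 higher adjusted over the list alone, median -0.23, adjusted p = 0.00318, and adjusted p = 0.307 with an estimated correlation).

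The fatty acid list was not among the 15 lists called for this interaction, and fat-7 had a larger effect in ire-1 (1.39, SE 0.25, adjusted p = 0.00082), from a level of 5.39 ± 0.13 there against 8.57 ± 0.32 in N2. Across clusters the RNAi effects in ire-1 and N2 correlated at 0.692 with a slope of 0.552 (0.008 in simulated arrays; covariance 0.199). Among the clusters called in N2, 64.8% of those that rose and 47.3% of those that fell were called in the same direction in ire-1, against 73.6% and 64.4% in atf-6 and 85% and 80.3% in pek-1.

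In the pek-1 mutant RNAi lowered pmt-2 by 2.90 (adjusted p = 1e-15), from 10.10 ± 0.07 to 7.2 ± 0.11. Here 5319 clusters rose and 7141 fell, and with cyclic loess 6174 were higher and 5385 lower. Rises were seen in pmt-1 (1.69), hsp-4 (0.99, SE 0.14, adjusted p = 1.8e-06), pek-1 (0.95), atf-6 (0.89), xbp-1 (0.75), hsp-3 (0.63) and atf-5 (0.51); ire-1 did not pass (-0.13, adjusted p = 0.301). Leading ranked genes were warf-1 (6.14), dbd-13 (5.73), kreg-1 (5.38), dpy-13 (4.95, SE 0.46), pud-3 (-4.62), pud-4 (-4.43), folt-2 (-4.30) and acdh-1 (-4.02). In the ER chaperone list 17 of 24 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.52, adjusted p = 3.9e-07, and adjusted p = 0.0607 with an estimated correlation). In the autophagy list 14 of 33 rose and 2 fell, also adjusted over the list alone (median 0.18, adjusted p = 0.000229, and adjusted p = 0.0607 with an estimated correlation). In the fatty acid list 22 of 33 rose and 4 fell (23 and 5 adjusted over the list alone, median 0.54, adjusted p = 4.13e-07, and adjusted p = 0.028 with an estimated correlation).

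The interaction with pek-1 was called for 353 clusters, 289 with a positive and 64 with a negative difference, and the effects in pek-1 and N2 correlated at 0.855 with a slope of 1.076 (0.001 in simulated arrays; covariance 0.387). Among ranked genes those of the cuticle led: col-88 (III: 41060-42017) differed by 3.30 (SE 0.51, adjusted p = 0.0008), bli-2 by 3.49 (SE 0.72), col-169 by 3.37 (SE 0.68) and col-162 by 3.27 (SE 0.76). Negative differences were those of srw-85 (-1.71, SE 0.41), ugt-4 (-1.18, SE 0.22), sysm-1 (-1.1, SE 0.26) and col-95 (-1.03, SE 0.21). In the collagen list 9 of 70 were higher and 2 lower (41 and 6 adjusted over the list alone, median 1.15, adjusted p = 3.34e-18, and adjusted p = 0.265 with an estimated correlation). In the molting list 6 of 36 were higher (24 adjusted over the list alone, median 1.43, adjusted p = 2.24e-20, and adjusted p = 0.167 with an estimated correlation). In the abu/pqn list 7 of 28 were higher (21 adjusted over the list alone, median 1.3, adjusted p = 1.79e-15, and adjusted p = 0.149 with an estimated correlation). For pmt-2 (0.61, adjusted p = 0.0613) and hsp-4 (0.41, adjusted p = 0.385) the test was not passed. A fit to only the 4 groups called 36. Without N2 RNAi array 1 the call stayed for 132 of the 353. The count was 1532 and 162 without N2 RNAi array 2 and 3, 200 without N2 empty-vector array 2, 224 without pek-1 empty-vector array 3, and 172 and 151 without pek-1 RNAi array 1 and 3. Without N2 RNAi array 1 bli-2 (2.81) and col-162 (2.47) were no longer called. Without pek-1 RNAi array 1 the calls of srw-85 (-1.74), sysm-1 (-1.13) and col-95 (-0.95) were lost, and those of col-162, srw-85 and sysm-1 also ended without several other arrays.

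**Figure D5:**
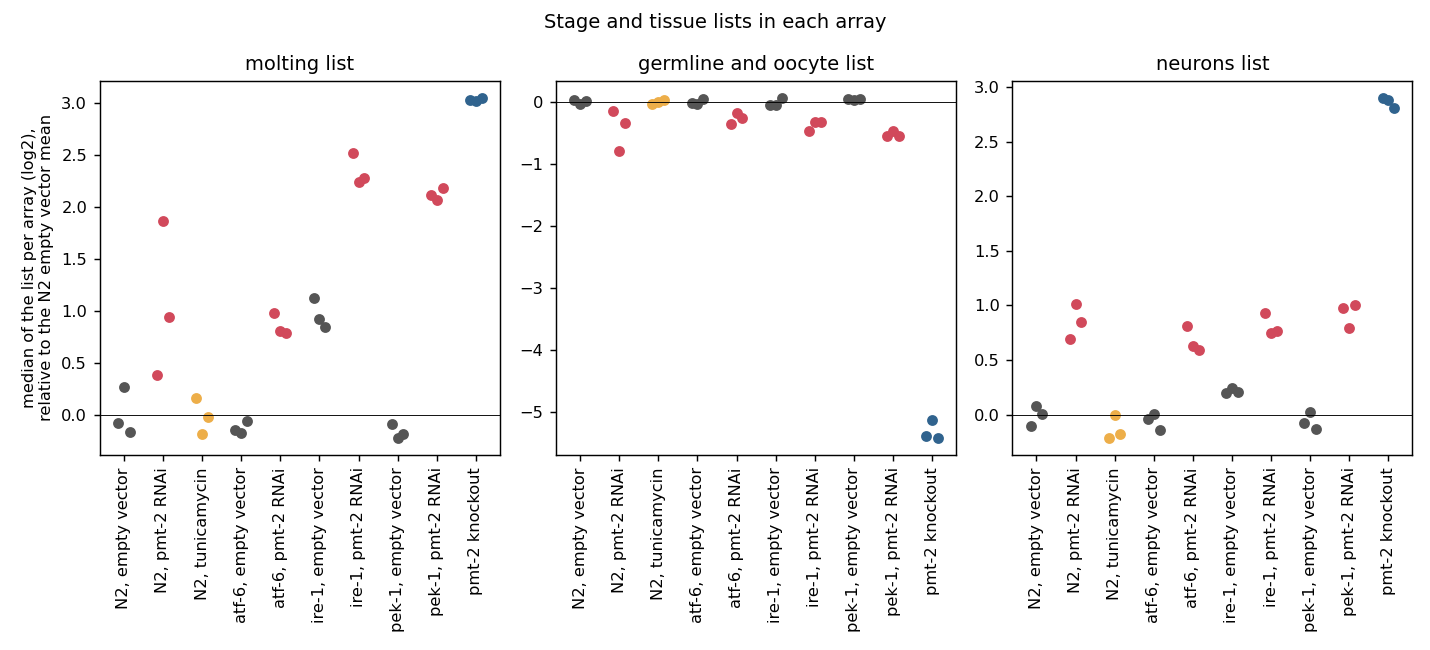
Median of the molting, germline and oocyte, and neuron lists in each array relative to the mean of N2 on the empty vector. Each group holds 3 arrays.

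The arrays differed in these markers. Relative to N2 on the empty vector the median of the molting list was 0.38, 1.87 and 0.94 in the N2 RNAi arrays, and 2.12, 2.07 and 2.18 in the pek-1 RNAi arrays. It was 0.98, 0.81 and 0.79 in the atf-6 RNAi arrays, 2.52, 2.24 and 2.28 in the ire-1 RNAi arrays and 3.03, 3.02 and 3.05 in the knockout. On the empty vector the ire-1 mutant stood at 1.12, 0.92 and 0.84. The germline list in the N2 RNAi arrays lay at -0.15, -0.80 and -0.35.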

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

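The tests of the 3 patterns weighed here and the second kind of split of the interactions were chosen after the results were seen, and the first splits were set before.

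Each comparison of a pair of groups was repeated on all 10 splits of its 6 arrays, and the real split called the most clusters in each (1 of 10, too few for a share under 0.05). The real counts with the highest other count were 9467 and 225 for pmt-2 RNAi in N2, 4715 and 3 for tunicamycin, 16807 and 0 for the knockout, 55 and 12 for the atf-6 mutant, 1748 and 1 for the ire-1 mutant and 32 and 2 for the pek-1 mutant. They were 8478 and 1, 7975 and 0, and 12460 and 1 for pmt-2 RNAi in atf-6, ire-1 and pek-1, 14616 and 1 for the knockout against RNAi, and 11279 and 42 for RNAi against tunicamycin.

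For the interactions with atf-6, ire-1 and pek-1 the real counts were 8, 1775 and 353. When treatments were exchanged within genotypes, 13, 16 and 18 of 100 splits called as many, with highest other counts of 8708, 7979 and 11712. Such splits place the RNAi effect itself in the interaction, so counts this far above the real ones point to a structure of the samples, and these splits do not single out the interaction. When genotypes were exchanged within treatments, 6, 1 and 4 of 100 splits called as many, with highest other counts of 203, 1280 and 362.

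A group of 15 clusters (14 distinct, as 2 have the same values in all arrays) was called in the same direction in all 3 sensor mutants, among them bcf-1 and gfi-1 (1448 bases apart), haf-6, fln-2 and srlf-30. For the group as a whole, chance values of the shared N2 empty-vector arrays are not a likely source. Those control arrays do not enter the difference between the mutant and N2 RNAi arrays. In the called direction this difference had a median of 0.689 over the 15 clusters (0.741 over the 14) and ran from 0.07 to 4.65. For clusters with a small difference, such as F12D9.12 and F46C5.13, chance values remain possible. Simulated arrays gave 0 shared clusters in 20 runs. The adjusted p calls almost nothing where no group changes, so those runs add no support. A strain difference between the N2 animals and the mutants remains a candidate explanation, with 11 of the 15 clusters (10 of the 14) fully apart in all RNAi arrays. The knockout was N2-like for bcf-1 (8.24) and gfi-1 (5.05) and like the mutants for haf-6 (5.0). However, haf-6 also fell in N2 with pmt-2 RNAi, from 6.87 to 5.89, so its knockout level does not bear on the strain difference. An effect of losing any sensor is not excluded, and outcrossed strains or sequencing around bcf-1 would test the strain difference.

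In the knockout the germline list lay at a median of -5.42 and the neuron list at 2.85. Neurons exceeded muscle, another somatic tissue, by 2.65 (95% interval 1.66 to 3.24 from 10000 resamples of genes), so these lists did not rise alike. A smaller share of germline tissue would raise them alike only if both respond equally on this scale. That was not tested, so such a share is not excluded as the whole cause. After cyclic loess, which moved muscle from 0.21 to 0.52, neurons still exceeded germline by 8.02 (95% interval 6.6 to 8.71, from resamples of genes). An offset between arrays cancels in this difference, with or without loess. The deposited arrays were already quantile normalised, so the test had little chance of another outcome, and no conclusion on scaling is drawn from it. Younger animals remain a candidate explanation, with 33 of 36 molting genes higher. Staging of the animals by gonad morphology would test this.

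In the interaction with pek-1, 9 of 70 collagen and 6 of 36 molting genes passed with a positive difference from N2, and neither list was called with an estimated correlation (adjusted p = 0.265 and 0.167). Across the 353 called clusters the interaction correlated at 0.672 with the difference between N2 RNAi arrays 2 and 1, against 0.452 across all clusters and 0.193 for the 1775 clusters of ire-1, so a spread of the N2 RNAi arrays along a developmental axis remains a candidate explanation. A sole N2 RNAi array also remains a possible explanation: at the preset correlation the molting list stayed called without any of the 3 (medians 0.91, 1.85 and 1.28), but 1, 26 and 1 of its genes passed. More N2 RNAi samples of known stage would separate an effect of pek-1 from the spread in stage.

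Several values of the interaction with ire-1 stood out. The autophagy list lay at -0.37 and the cytochrome P450 and UDP-glucuronosyltransferase list at 0.33. The differences were -0.64 for hsp-4, whose call was lost after a shift to a common median (-0.57) and without most single arrays, -0.74 for pmt-1 and 1.33 for pmt-2. They were 3.96 for pud-3, 3.53 for pud-4, 3.27 for vit-1 and 3.03 for dhs-26, and -3.95 for warf-1, -3.78 for tbb-6, -3.75 for asp-17 and -3.57 for kreg-1. As RNAi lowered pmt-2 less in ire-1 than in N2, these values do not separate a weaker knockdown from loss of ire-1. Levels on the empty vector also enter them, and there tbb-6 and warf-1 were already higher in ire-1 than in N2. The molting list stood at 1.12, 0.92 and 0.84 in the ire-1 empty-vector arrays relative to N2, so a difference in stage is not separated either.

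In the interaction with atf-6 the differences were 1.82 for bcf-1, 1.65 for acdh-2, 1.25 for swt-3 and 0.97 for nhr-43. In that with pek-1 they were 3.49 for bli-2, 3.37 for col-169, 3.3 for col-88 and 3.27 for col-162, and -1.71 for srw-85, -1.18 for ugt-4, -1.1 for sysm-1 and -1.03 for col-95.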

How the results depend on the processing

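The tests with array weights by gene and the gene lists and overlaps without each array were chosen after results were seen. Probe-level files were not used here, so signal over background was not tested and values near the floor of the arrays limit the size of any rise or fall. Over the alternatives, of 15515 values for named genes with a call 14909 kept it and 606 lost it, and of 8446 without a call 282 gained one. Many named genes were picked for large changes in these same data, and each counts in many overlapping refits. The share that kept a call therefore does not apply to other clusters. Of 1456 values for gene lists with a call 1201 kept it and 255 lost it, and of 1386 without a call 80 gained one and 2 gained one in the opposite direction. The latter were phosphatidylcholine and one-carbon metabolism for pmt-2 RNAi in atf-6 with fry (adjusted p = 0.00638) and ribosomal proteins in the knockout with cyclic loess (adjusted p = 4.5e-05), and the cause was not tested.

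A fit to only the groups of a comparison has fewer samples for the spread. It called 5634 clusters for pmt-2 RNAi in N2 (9467 in the full fit), 2970 for tunicamycin (4715), 5, 834 and 5 for the atf-6, ire-1 and pek-1 mutants (55, 1748 and 32), 0, 1096 and 36 for their interactions (8, 1775 and 353) and 7488 for RNAi against tunicamycin (11279). With as many arrays, RNAi in ire-1 and pek-1 had 7957 and 11571 calls (7975 and 12460 in the full fit). The full fit gives all groups the same spread per cluster. The median SD was largest in the N2 RNAi group (0.194, against 0.142 and 0.147 in the ire-1 and pek-1 RNAi groups). That N2 group is not part of the tunicamycin and mutant comparisons, which lost calls as well. With the low SDs of their RNAi groups, the ire-1 and pek-1 comparisons do not show how far sample number accounts for the losses. A fold of at least 1.5 leaves fewer genes: 5615 for RNAi in N2, 1130 for the ire-1 mutant (1748), 4858, 4265 and 8203 for RNAi in atf-6, ire-1 and pek-1 (8478, 7975 and 12460), and 6889 for RNAi against tunicamycin. With 1 cluster per gene, which tests fewer clusters, the atf-6 interaction had 1 call, and with cyclic loess 5 (the cause was not tested).

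With a weight per array there were 95 calls for the atf-6 mutant and 262, 4936 and 3002 for the interactions with atf-6, ire-1 and pek-1. That estimate of the weights had not converged. With weights estimated gene by gene they were 100, 62, 3863 and 2115. Both gave N2 pmt-2 RNAi array 3 a far higher weight than its replicates (27.372 and 5.824), and beyond this the cause was not tested.

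After a shift to a common median the atf-6 mutant had 16 clusters higher and 54 lower, the ire-1 mutant 638 and 1390, and the ire-1 interaction 1099 and 676. The median change in the knockout was -0.133 as deposited, -0.256 after this shift and -0.091 with cyclic loess. With an estimated correlation 39 of the 208 list calls at the preset correlation remained, and the cause was not tested.

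Without each array in turn the atf-6 mutant had 25 to 69 calls, the atf-6 interaction 0 to 11 and the pek-1 interaction 1.5e+02 (rounded, without N2 RNAi array 1) to 1532 (without array 2). Correlations with pmt-2 RNAi in N2 ran from 0.541 to 0.613 for the knockout, 0.589 to 0.736 for RNAi in ire-1 and 0.779 to 0.877 for RNAi in pek-1. For atf-6 it was 0.923 over only clusters called in either (0.874 over all). Leaving out an array leaves fewer samples, and beyond this the cause was not tested.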

Other observations

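The tests in this part were set before results were seen, except that the lists and genes described were picked from those left over.

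Lists of tRNA synthetases and of the proteasome fell with pmt-2 RNAi in N2 and in the knockout. With RNAi 15 of 24 tRNA synthetase genes fell (15 adjusted over the list alone; median -0.34, adjusted p = 4.53e-05; adjusted p = 0.13 with an estimated correlation), with fars-1 at -0.72, and 17 of 31 proteasome genes (17 lower and 1 higher adjusted over the list alone; median -0.24, adjusted p = 0.000794; adjusted p = 0.364 with an estimated correlation), with pas-5 at -0.70. Of 79 ribosomal protein genes 36 fell and 5 rose (37 and 6 adjusted over the list alone; median -0.18, adjusted p = 0.00154; adjusted p = 0.576 with an estimated correlation; adjusted p = 0.0593 with cyclic loess). N-glycosylation genes fell in 14 of 22 cases and rose in 4, also adjusted over the list alone (median -0.35, adjusted p = 0.0233; adjusted p = 0.364 with an estimated correlation; adjusted p = 0.056 with cyclic loess). In the mitochondrial stress list 12 of 21 fell and 3 rose, also adjusted over the list alone (median -0.46, adjusted p = 0.0143; adjusted p = 0.143 with an estimated correlation). In the knockout all 31 proteasome genes fell (31 adjusted over the list alone; median -0.95, adjusted p = 4.34e-10; adjusted p = 0.117 with an estimated correlation), as did 21 of 24 tRNA synthetase genes with 1 higher (21 and 1 adjusted over the list alone; median -0.88, adjusted p = 1.81e-05; adjusted p = 0.0973 with an estimated correlation). The ribosomal protein list was not called there (16 of 79 lower, 2 higher; 13 and 2 adjusted over the list alone; median -0.05, adjusted p = 0.552), and with cyclic loess it was called higher (adjusted p = 4.5e-05).

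With pmt-2 RNAi in N2 lists of detoxification and yolk genes fell and that of the cytosolic heat shock response rose. In the cytochrome P450 and UDP-glucuronosyltransferase list 22 of 47 fell and 8 rose (24 and 8 adjusted over the list alone; median -0.42, adjusted p = 0.00525; adjusted p = 0.184 with an estimated correlation), with ugt-63 at -2.83, and of the vitellogenins 3 of 5 fell, also adjusted over the list alone (median -1.06, adjusted p = 0.00439; adjusted p = 0.197 with an estimated correlation). In the heat shock list 6 of 20 rose, also adjusted over the list alone (median 0.12, adjusted p = 0.0337; adjusted p = 0.197 with an estimated correlation), with hsp-43 at 1.4. The innate immune list was not called in N2 (19 of 56 higher, 11 lower; median -0.07, mean 0.29, adjusted p = 0.0775) and rose in the knockout (35 of 56 higher, 10 lower; 35 and 11 adjusted over the list alone; median 0.76, adjusted p = 0.000483; adjusted p = 0.105 with an estimated correlation). Beta-oxidation (median 0.00, adjusted p = 0.628) and lysosome (median -0.16, adjusted p = 0.091) were not called with RNAi in N2, and the oxidative stress and glutathione list was called in none of the 14 comparisons (adjusted p from 0.0801 to 0.963).

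In the comparison tables of the submitters, 2860 clusters had an FDR under 0.05 for pmt-2 RNAi in N2, 1710 for tunicamycin and 14574 for the knockout, of which 2730, 1562 and 14020 were called here in the same direction. For the atf-6, ire-1 and pek-1 mutants the numbers were 6, 299 and 0, of which 3, 230 and 0 were called here in the same direction. For RNAi in atf-6, ire-1 and pek-1 they were 5323, 5800 and 9454, of which 4849, 5071 and 8906 were. No cluster of these tables was called here in the opposite direction.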
